A study of Arabidopsis thaliana with 12 samples.

How the data were processed

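RNA was sequenced from the first leaves of Arabidopsis thaliana seedlings grown for 14 days on MS plates with 1% sucrose, extracted with RNeasy columns, made into libraries with the TruSeq RNA v2 kit, which does not mark the strand, and read on an Illumina HiSeq instrument. The 12 libraries were 4 of Col-0 and 2 each of the other accessions (Per-1, Aa-0) and of the hybrids (Col-0×Per-1 and Col-0×Aa-0), grouped by the sample labels alone. The series description names Ler-1 and duplicates where the sample labels name Per-1 and 4 Col-0 libraries, and the sample labels were followed.

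The values analysed were FPKM as deposited by the authors, written to 2 decimals. Per the submitters' processing notes, TopHat2 2.0.8b, TopHat, Cufflinks 2.0.2, edgeR 3.12.0 and the TAIR10 genome were used. Which of them made the FPKM, the filters and the total used for scaling are not given in the sources used here. The files held 34133 identifiers, of which 8532 were at 0 in every library. Names and overlaps between genes were taken from a TAIR10.1 annotation, where 31416 identifiers were found and 2717 were not, and no coordinates are reported.

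The fit was made with R 4.3.3 and limma 3.58.1 on log2(FPKM + 1) for the 17203 genes with at least 1 FPKM in at least 2 libraries. A group-means model of all 12 libraries left 7 residual degrees of freedom, and eBayes was run with a trend. Changes were called at a Benjamini-Hochberg adjusted p under 0.05. The mid-parent was the log2 of the mean of the parents' fitted values, with standard errors by the delta method. The difference between the hybrids' deviations took account of the Col-0 libraries that both share. A gene outside both parents passed against each parent in the same direction. Levels in the hybrid relative to the parents were classed from the same contrasts, with exact binomial and Fisher tests that treat genes as independent. A gene was put at the level of 1 parent when it differed from the other parent alone. Col-0 had 4 libraries and the other parent had 2, so a gene midway differs more easily from Col-0. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.

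The genes named were chosen by a rule written before the data were examined. For each parent contrast, each mid-parent contrast and the difference between hybrids, it took the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 FPKM. Between parents the library values had not to overlap, and both hybrid libraries had to lie on the same side of the mid-parent. Up to 3 called members of each list with the smallest adjusted p were added, and CCA1, LHY, FLC, PR1, WUS and ARGOS in every case. Members named because a count was 5 or fewer, the members named for contrasts outside the rule, LHY in single libraries, UBQ6 and RBCS1A were chosen after their values were seen.

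Of 24 lists fixed in advance from general knowledge, with 392 genes beside the organelle-encoded ones, 12 of these genes had no symbol in the reference and 0 conflicted with it. The members tested, of those in the files, were: salicylic acid and immune response 21 of 24, NLR immune receptors 24 of 25, jasmonate and wounding 18 of 19, glucosinolate metabolism 22 of 23, photosynthesis 34 of 34, chlorophyll biosynthesis 18 of 18, cell cycle and DNA replication 24 of 35, leaf growth regulators 22 of 28, cytosolic ribosomal proteins 21 of 21, circadian clock 20 of 20, flowering time 10 of 15 and auxin response and synthesis 17 of 20. The others were cold, drought and abscisic acid response 24 of 24, heat shock 6 of 8, flavonoid and anthocyanin synthesis 7 of 17, sugar status 11 of 12, leaf senescence 7 of 8, stomatal lineage 5 of 8, vascular markers 9 of 9, plastid-encoded genes 77 of 133 and mitochondrially encoded genes 24 of 146. Root markers (1 of 9), shoot meristem markers (0 of 7) and trichome markers (2 of 8) had too few members for a test. Lists were tested with cameraPR (preset correlation 0.01, adjusted over the 21 lists of a comparison), and beside it with camera and an estimated correlation and with fry, both of which used the mean of the parents' log2 values as mid-parent. The camera tests set a list against the other genes, while fry sets it against no change.

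Depth relative to Col-0 replicate 1 was read from genes above 0 in at most 8 libraries, with FPKM from 0.08 to 2 in both libraries compared. It was the most frequent ratio of the value in Col-0 replicate 1 to that in the library, such values being taken as about 1 read each. It was 1, 1.11, 1.11 and 1.11 in Col-0, 1 and 0.9 in Aa-0, 0.9 and 1 in Per-1, 1 and 1.11 in Col-0×Aa-0, and 0.84 and 0.66 in Col-0×Per-1. On simulated data with 100 genes changed by log2 1 and 100 by log2 2, 73% and 97% were recovered between Aa-0 and Col-0 with 6 false calls. The figures were 82% and 95% for Col-0×Aa-0 against the mid-parent (3 false calls), 0 false calls for a hybrid at its mid-parent, and 52% and 92% for the difference between hybrids (4 false calls). The delta-method error was 0.984 times the spread of 40 repeated draws of 300 genes. A simulated list moved by 0.5 was called and 0 others were. These simulations drew every gene and library independently. They lack correlation within lists and differences between pairs of Col-0 libraries, so they do not show how many calls in the real data are false.

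Alternatives were log2(FPKM + 0.1), no filter, a mean of at least 5 FPKM, TPM, median-ratio and quantile scaling, eBayes without trend or robust, only the groups needed, either pair of Col-0 libraries (1 and 2, or 3 and 4), the replicate number as a block, the mean of log2 values as mid-parent, a log2 difference of at least 1, other bounds for genes near 0 in 1 parent (0.5 and 10 FPKM), and each library left out in turn. Leaving out genes that overlap another annotated gene, and the photosynthesis list without RBCS1A, were added after the data were seen.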

Results

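First leaves of 14-day-old Arabidopsis thaliana seedlings were profiled by RNA sequencing in the natural accessions Col-0 (4 libraries), Aa-0 (2) and Per-1 (2), and in the hybrids Col-0×Aa-0 (2) and Col-0×Per-1 (2). Values were FPKM, a measure of fragments scaled by transcript length and library size. Between 20772 and 21781 genes had a value above 0 per library, and 17203 genes were tested. Absolute depth is unknown, as the values used here are not counts. The depth relative to Col-0 replicate 1, read from the ratios of low values between libraries, ran from 0.66 in Col-0×Per-1 replicate 2 to 1.11 in 4 libraries. The labels do not say that replicates came from separate plants, so each p-value measures only the spread between these samples, which may be technical.

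The first 2 principal components held 34.2% and 22.9% of the variance. On the first, the Col-0 libraries lay between -45.30 and -33.15, the Per-1 libraries at 39.69 and 45.34, and each hybrid library between its parents. The Col-0 libraries themselves differed: the clock gene LHY was listed at 50.6 and 51.5 FPKM in replicates 1 and 2 and at 1.57 and 1.85 FPKM in replicates 3 and 4. RBCS1A, a small subunit of Rubisco, was listed at 0 in Col-0 replicates 1 and 2, at 19509 and 19500 FPKM in Col-0 replicates 3 and 4, and between 16409 and 25067 FPKM in the other 8 libraries. Col-0×Per-1 replicate 2 had the lowest median level of tested genes, 3.01 on the log2(FPKM + 1) scale against 3.14 to 3.42 in the other libraries, and the highest shares of plastid-encoded (5.76%) and mitochondrially encoded (0.126%) transcripts.

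**Figure D1:**
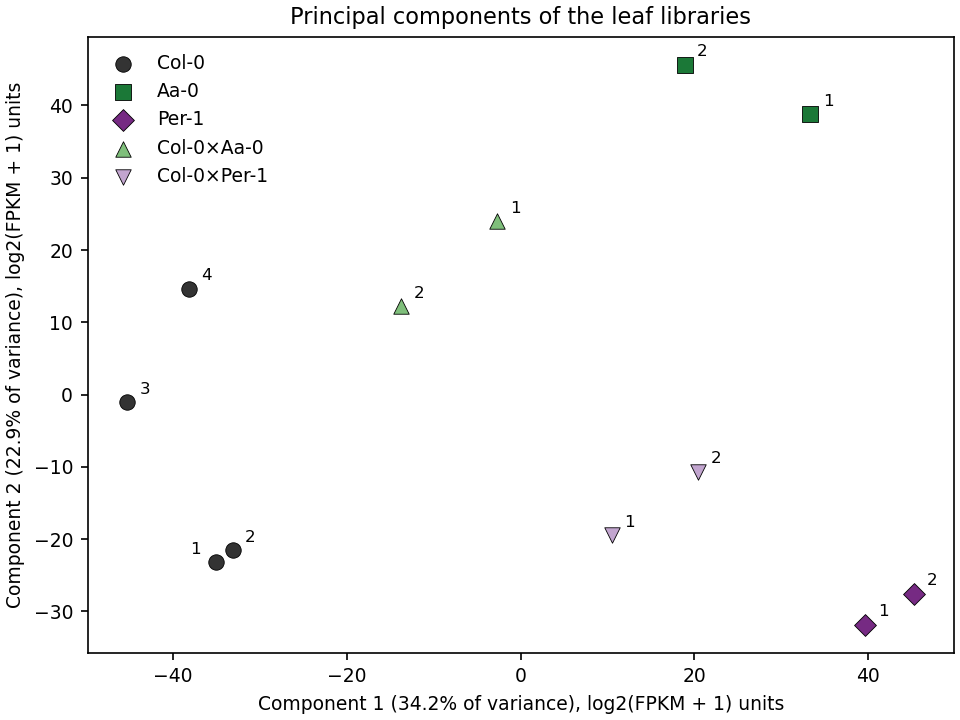
Scores of the 12 libraries on principal components 1 and 2 of log2(FPKM + 1), with 1 point per library, shape and colour by group and the replicate number beside it. Each hybrid lies between its parents on component 1, and the Col-0 libraries spread from -23.21 to 14.64 on component 2.

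The first comparison asked how the Aa-0 parent differed from the common Col-0 parent. HPL1 was listed at 113 ± 4.1 FPKM in Aa-0 (SD, n = 2) and 1.26 ± 0.395 in Col-0 (SD, n = 4). ESP (AT1G54040), the epithiospecifier protein that directs glucosinolate breakdown towards nitriles, stood at 752 ± 20.4 against 20.3 ± 1.16 FPKM. Going the other way, ECS1 was at 0.185 ± 0.0354 FPKM in Aa-0 and 738 ± 164 in Col-0, and AT3G62530 at 0.025 ± 0.0354 against 188 ± 18.5. The log2 differences were 5.67 ± 0.19 for HPL1 (standard error, adjusted p = 3.9e-08), 5.14 ± 0.11 for ESP, -9.26 ± 0.24 for ECS1 (adjusted p = 5.0e-09) and -7.52 ± 0.12 for AT3G62530. The TAIR10 genome named in the processing notes is that of Col-0. Low values in an accession, here and for Per-1 below, may therefore also reflect sequence that differs from the reference. Single genes were not tested for this.

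Immune receptor genes of the nucleotide-binding leucine-rich repeat class (NLR) were lower in Aa-0: 13 of 24 tested members fell, NRG1.2 rose, and 10 did not pass. RPP2A and RPP2B, which together give resistance to downy mildew in Col-0, fell from 13.8 ± 1.33 and 12.6 ± 2.02 FPKM to a listing of 0 in both Aa-0 libraries and to 0.22 ± 0.0283. RPM1, a receptor for bacterial effectors, fell from 4.72 ± 0.973 FPKM and was also listed at 0 in both Aa-0 libraries, although it overlaps another annotated gene. The list test passed (adjusted p = 9.12e-13; adjusted p = 0.587 with an estimated correlation), and 15 members fell when adjusted over the list alone. Of 22 glucosinolate genes 14 fell, among them ESM1 (542 ± 92.2 to 39.8 ± 2.74 FPKM) and CYP79F2 (2.73 ± 0.528 to 0.325 ± 0.0636), while ESP rose. That list did not pass its test (adjusted p = 0.0742), and adjusted over the list alone 15 fell and 2 rose.

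Among 18 jasmonate and wounding genes 6 were lower in Aa-0, including the storage protein gene VSP2 (log2 difference -2.44 ± 0.35) and the lipoxygenase gene LOX3 (-2.69 ± 0.43), with 7 lower and 2 higher when adjusted over the list alone and a list adjusted p of 0.661. PDF1.2, a defensin gene, passed at an adjusted p of 0.012 but not without Aa-0 replicate 1 (0.0878) or replicate 2 (0.0577). Genes for cytosolic ribosomal proteins fell in 9 of 21 cases, 19 when adjusted over the list alone, by a list median of -0.61 (adjusted p = 0.0434; adjusted p = 0.587 with an estimated correlation). RPS15 stood at 102 ± 16.4 against 178 ± 11.4 FPKM and RPS6B at 83.1 ± 19.8 against 136 ± 5.71. Both calls (adjusted p = 0.101 and 0.137) and the list's (0.285) ended without Aa-0 replicate 1. The list's call also ended without Col-0 replicate 1 (0.070), replicate 2 (0.068) or replicate 4 (0.0536). In the cell cycle list CYCD3;2, a D-type cyclin that overlaps another gene, fell from 19.4 ± 0.534 to 5.93 ± 1.05 FPKM and CYCB2;3 rose from 1.01 ± 0.328 to 5.42 ± 0.509, with 6 of 24 members lower and 2 higher (list adjusted p = 0.61). Plastid-encoded genes were higher as a list (adjusted p = 0.000395; adjusted p = 0.587 with an estimated correlation), with 6 of 77 rising.

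In all, 2870 genes differed between Aa-0 and Col-0 by limma, 812 higher and 2058 lower in Aa-0, and the median over all tested genes was -0.14. Median-ratio scaling of the libraries gave 1271 higher and 1280 lower and quantile normalization 1366 and 1091, and both methods centre the libraries. Without Aa-0 replicate 1 the count was 1218.

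The Per-1 parent was set against Col-0 in the same way. FLC, the repressor of flowering that vernalization silences, was at 48.1 ± 8 FPKM in Per-1 (SD, n = 2) and 0.075 ± 0.125 in Col-0 (SD, n = 4), a log2 difference of 5.51 ± 0.14 (standard error, adjusted p = 4.7e-09). SOC1, a flowering activator repressed by FLC, fell from 41.6 ± 1.99 to 12.7 ± 4.32 FPKM. MAM3, which elongates the chains of methionine-derived glucosinolates, rose from 0.388 ± 0.0714 to 43.4 ± 4.36 FPKM, and TGG2, a myrosinase that hydrolyses glucosinolates, fell from 247 ± 16.8 to 0.355 ± 0.0354. AT5G41660 was listed at 0 in all 4 Col-0 libraries and stood at 31.0 ± 4.77 FPKM in Per-1, and AT2G25510 went from 710 ± 179 to 0.09 ± 0.127.

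Genes of the salicylic acid and immune response were higher in Per-1, where 11 of 21 rose and none fell. EDS1, a central regulator of immune signalling, rose from 8.90 ± 1.5 to 22.5 ± 3.53 FPKM, the β-glucanase gene BGL2 from 2.50 ± 1.13 to 32.0 ± 7.36, and NUDT6 from 1.08 ± 0.418 to 6.14 ± 1.02. PR1, the standard marker of the salicylic acid response, was at 26.0 ± 21.7 FPKM against 0.637 ± 0.749 (adjusted p = 0.00422), a call lost without Per-1 replicate 1 (0.0618). The list passed (adjusted p = 4.61e-06; adjusted p = 0.659 with an estimated correlation), with 13 higher when adjusted over the list alone. Of 24 NLR genes 11 fell, 2 rose (NRG1.2 and RPP2B) and 11 did not pass. RPP2A fell to 0.01 ± 0.0141 FPKM and RPP8 from 54.2 ± 6.10 to 13.6 ± 0.0849. That list passed as well (adjusted p = 0.000217; adjusted p = 0.659 with an estimated correlation), with the same counts when adjusted over the list alone.

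Genes of DNA replication and the cell cycle were lower in Per-1 in 11 of 24 cases, with CYCB2;3 higher. PCNA2, the sliding clamp of DNA polymerase, fell from 7.11 ± 0.620 to 1.76 ± 0.707 FPKM, and CDC6, which loads the replicative helicase, from 2.38 ± 0.499 to 0.385 ± 0.148. Both overlap another annotated gene. The list did not pass (adjusted p = 0.148), with 15 lower when adjusted over the list alone. Of 10 flowering time genes 6 fell and only FLC rose (list adjusted p = 0.419), the fallen ones including MAF4, listed at 0 in both Per-1 libraries against 1.31 ± 0.318 FPKM. The glucosinolate list split evenly, 6 members higher and 6 lower of 22, and its median (0.22) and mean (-0.22) had opposite signs. Vascular markers fell in 4 of 9 cases, among them PP2-A1, a phloem lectin (122 ± 10.8 to 50.3 ± 0.445 FPKM), and XCP2, a xylem protease (44.6 ± 2.43 to 21.9 ± 3.1), with a list adjusted p of 0.148. Jasmonate genes ORA59 and JAZ10 rose (list adjusted p = 0.082), both calls being lost without Per-1 replicate 1 (adjusted p = 0.0599 and 0.106).

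The other lists did not pass in Per-1 (adjusted p): ribosomal proteins 0.258 with 9 of 21 lower, photosynthesis 0.0507, chlorophyll biosynthesis 0.793, leaf growth 0.831, clock 0.734, auxin 0.793, cold and drought 0.627, heat shock 0.734, flavonoids 0.804, sugar status 0.627, senescence 0.789, stomatal lineage 0.793, and plastid-encoded (0.0933) and mitochondrially encoded genes (0.276). Among leaf growth regulators ARL rose and TCP3, TCP2, TCP4 and EBP1 fell, with TCP2 lost without Per-1 replicate 1 (0.1) and EBP1 without Per-1 replicate 1 (0.0534) or 2 (0.126).

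Between Per-1 and Col-0 4426 genes differed by limma, 1061 higher and 3365 lower, with a median shift of -0.19 over all tested genes. With median-ratio scaling 1764 were higher and 1601 lower, and with quantile normalization 1628 and 1562. The count was 1807 without Per-1 replicate 1 and 1816 without replicate 2.

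**Figure D2:**
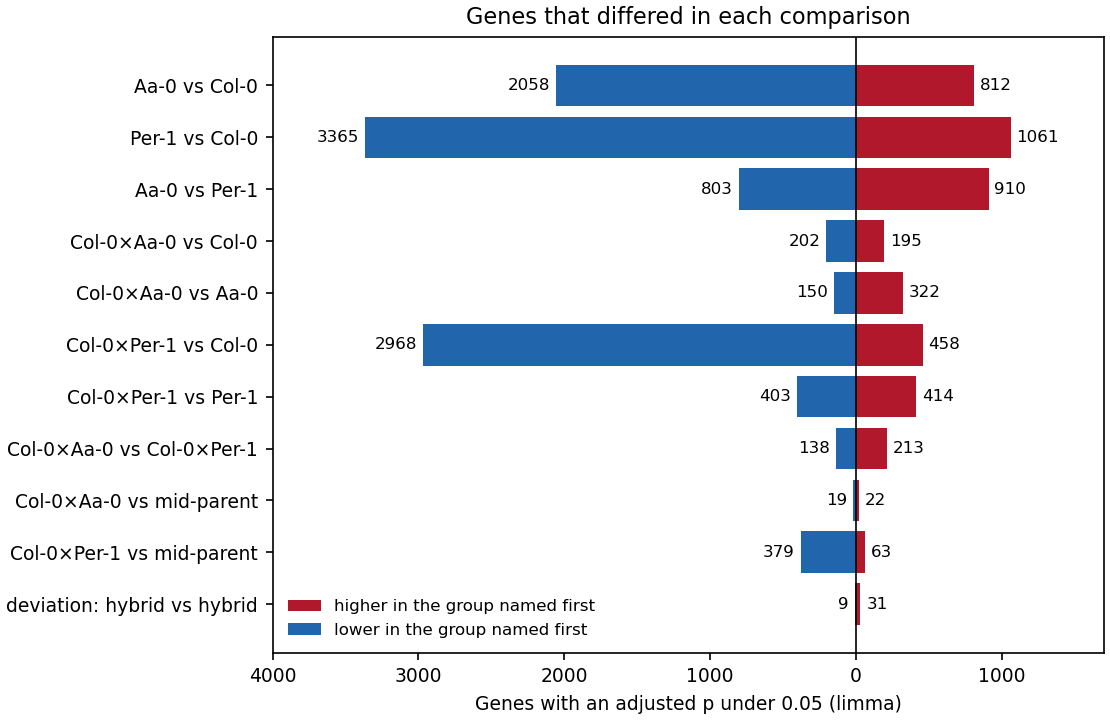
Number of genes with an adjusted p under 0.05 (limma, x axis) in each of the 11 comparisons (y axis), drawn to the right where higher and to the left where lower in the group named first, on the FPKM as deposited. Per-1 against Col-0 had the most, 4426, and the deviations of Col-0×Aa-0 from the mid-parent numbered 41. With median-ratio scaling the 3365 lower genes of Per-1 became 1601 and the 2968 of Col-0×Per-1 against Col-0 became 865.

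Heterosis concerns hybrids that exceed their parents, so each hybrid was next set against both parents and against the mid-parent, the mean of the parental levels. In Col-0×Aa-0, several genes named above had means between those of the parents: HPL1 was at 47.7 ± 13.0 FPKM (SD, n = 2), ESP at 513 ± 18.1, ECS1 at 385 ± 133 and RPP2A at 5.83 ± 0.566. By limma 41 genes deviated from the mid-parent, 22 above and 19 below. The count was 44 with median-ratio scaling, but 374 with Col-0 replicates 1 and 2 alone as the parent, 233 with the replicate number as a block and 114 with the mean of the parents' log2 values. Above it were AT3G52070, at 14.8 ± 1.61 FPKM in the hybrid, 9.95 ± 0.991 in Col-0 and 0.455 ± 0.106 in Aa-0, and MRD1 (13.2 ± 0.269, 8.70 ± 0.559 and 0.775 ± 0.530). Below it were the glycosyltransferase gene HYR1, at 5.34 ± 0.460 FPKM in the hybrid, 6.72 ± 1.08 in Col-0 and 32.1 ± 2.38 in Aa-0, and AT5G63195 (4.50 ± 0.438, 3.46 ± 0.491 and 34.7 ± 7.77). All 4 overlap another annotated gene, as did 28 of the 40 deviating genes found in the reference, and without overlapping genes 5 deviated.

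No gene list passed with an estimated correlation in Col-0×Aa-0 against the mid-parent. With the preset correlation the glucosinolate list was above it (median 0.14, adjusted p = 0.000605; adjusted p = 0.286 with an estimated correlation) although 0 of 22 members passed singly, 1 when adjusted over the list alone. Flowering genes were below it (adjusted p = 0.0063; adjusted p = 0.286 with an estimated correlation), with MAF5, a relative of FLC, the 1 member that passed, below its levels of 6.38 ± 1.81 FPKM in Col-0 and 2.63 ± 0.198 in Aa-0 (log2 difference from the mid-parent -1.28 ± 0.20, adjusted p = 0.042, lost under 10 of the 12 omissions of a library). Adjusted over the list alone 3 members were below. The glucosinolate call was lost without Col-0×Aa-0 replicate 1 (0.983) and the flowering call without replicate 2 (0.649). Photosynthesis (adjusted p = 0.000605; adjusted p = 0.72 with an estimated correlation) and immune genes (0.0203; adjusted p = 0.927 with an estimated correlation) were also above the mid-parent as lists, and cell cycle (0.0167; 0.927), stomatal lineage (0.00957; 0.286) and plastid-encoded genes (0.0158; 0.944) below it, with 0 members passing singly. The first was lost without Col-0×Aa-0 replicate 1 (0.986) and the other 4 without its replicate 2 (0.973, 0.649, 0.649 and 0.931).

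Against its parents, Col-0×Aa-0 differed from Col-0 in 397 genes (195 higher, 202 lower; 249 and 133 with median-ratio scaling; 2351 genes with Col-0 replicates 1 and 2 alone and 1888 with the block) and from Aa-0 in 472 (322 higher, 150 lower). Of 24 NLR genes 5 were below Col-0 (ADR1, RPP2B, RPP2A, RPM1 and SNC1; list adjusted p = 6.53e-05; adjusted p = 0.812 with an estimated correlation) and 9 above Aa-0 (adjusted p = 3.6e-12; adjusted p = 0.198 with an estimated correlation), or 10 and 12 when adjusted over the list alone. Both parents were exceeded by 8 genes and undercut by 0, with 5 such genes, all above, when overlapping genes were left out. Of the 2870 genes that differed between these parents, 333 were at the level of the higher parent, 178 at that of the lower, 165 between and different from both, and 2190 were not resolved. The low-parent share of the resolved pair of classes was 34.8% (exact binomial 95% interval 30.7 to 39.1%, treating genes as independent, p = 6.66e-12), 29.7% where Col-0 was the higher parent and 41.2% where it was the lower, but 58.2% with Col-0 replicates 1 and 2 alone as the parent.

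The small count rested on few libraries. Without Col-0×Aa-0 replicate 1 or 2, 5 or 4 genes deviated from the mid-parent, without Aa-0 replicate 1 it was 19, and without either Per-1 library, which enters only the spread, 23. It was 27 without either Col-0×Per-1 library. Without either of its own libraries 156 genes differed from Col-0, against 397, and with replicate 1 left out 291 differed from Aa-0. The genes above both parents then numbered 2 or 1.

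Col-0×Per-1 was set against its parents in the same way. FLC stayed high, at 36.8 ± 3.10 FPKM (SD, n = 2; log2 difference from the mid-parent 0.60 ± 0.16, adjusted p = 0.0725), and SOC1 was at 16.3 ± 0.785. Several genes that were high in Per-1 and low in Col-0 stayed far below the Per-1 level. AT5G41660 was at 0.02 ± 0.0283 FPKM (log2 difference from the mid-parent -4.01 ± 0.12, adjusted p = 2.8e-07), MAM3 at 2.15 ± 0.269 (-2.86 ± 0.12, adjusted p = 2.9e-06), and HPL1 at 3.06 ± 0.0707, although Per-1 had 62.0 ± 11.1. AOP2, which forms alkenyl glucosinolates, was at 0.760 ± 0.325 FPKM in the hybrid, 3.73 ± 0.913 in Col-0 and 28.9 ± 5.20 in Per-1 (-3.30 ± 0.23, adjusted p = 0.00018). AT2G04170 was above both parents, at 23.8 ± 1.26 FPKM against 3.37 ± 0.242 and 7.89 ± 1.94.

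**Figure D3:**
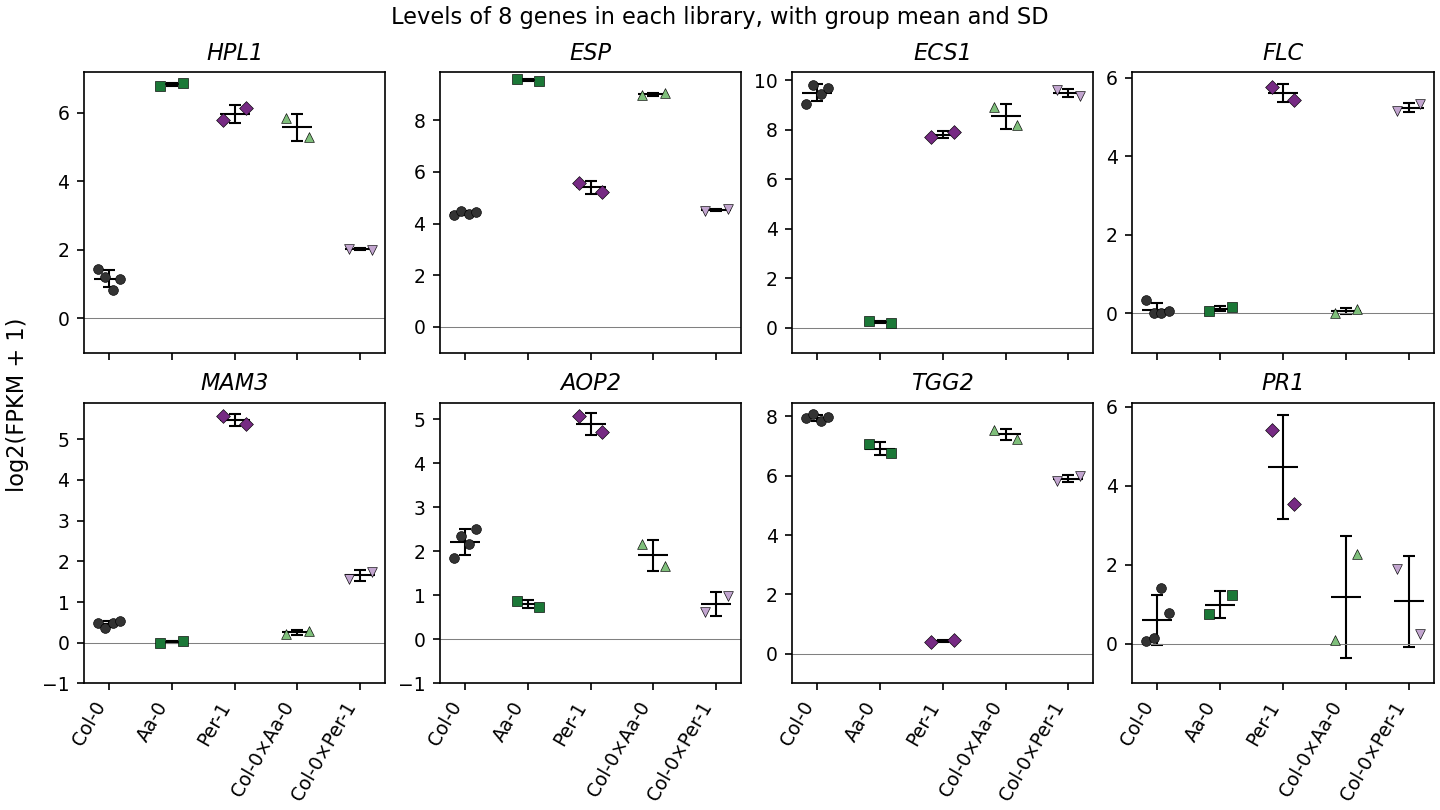
log2(FPKM + 1) of 8 genes (y axis) in each library by group (x axis), with points for libraries and a horizontal mark with bars for the group mean and SD of those log2 values (n = 4 for Col-0, 2 otherwise). FLC is high in Per-1 and Col-0×Per-1, with mean levels of 48.1 and 36.8 FPKM, while MAM3, at 43.4 FPKM in Per-1, is at 2.15 FPKM in Col-0×Per-1.

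Glucosinolate genes lay below the mid-parent in Col-0×Per-1: 10 of 22 were lower, ESM1 was higher, and 14 were lower when adjusted over the list alone (list median -0.91, adjusted p = 2.78e-20; adjusted p = 0.456 with an estimated correlation). CYP79F2, which starts the synthesis of aliphatic glucosinolates, was at 1.04 ± 0.255 FPKM against 2.73 ± 0.528 in Col-0 and 5.73 ± 1.06 in Per-1. Jasmonate genes were lower as a list (median -1.14, adjusted p = 0.00136; adjusted p = 0.499 with an estimated correlation), with JAZ10 and OPR3 passing singly and 9 of 18 when adjusted over the list alone. Both single calls were marginal, at adjusted p = 0.039 and 0.047, and each was lost under 10 of the 12 omissions of a library. Ribosomal protein genes were lower (3 of 21, namely RPS6A, RPL9C and RPL5A; 11 when adjusted over the list alone; adjusted p = 3.53e-05; adjusted p = 0.54 with an estimated correlation), and so were cell cycle genes (MCM7 and MCM3 of 24; 8 when adjusted over the list alone; adjusted p = 0.00906; adjusted p = 0.54 with an estimated correlation). None of those 5 single calls held with median-ratio scaling. The cell cycle list was lost without Col-0×Per-1 replicate 1. By cameraPR it was also lost with Col-0 replicates 1 and 2 alone (adjusted p = 0.0965) or the replicate number as a block (0.0792).

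Photosynthesis genes lay above the mid-parent as a list (median 0.16, adjusted p = 1.31e-06; adjusted p = 0.456 with an estimated correlation), with 0 of 34 members passing singly, also when adjusted over the list alone. Quantile normalization ended that call (0.318), and it held without RBCS1A. Mitochondrially encoded genes were also above it (median 0.24, adjusted p = 4.33e-09; adjusted p = 0.456 with an estimated correlation), in the hybrid whose replicate 2 had the highest mitochondrial share. Plastid-encoded genes passed upwards (adjusted p = 0.000179; adjusted p = 0.718 with an estimated correlation) with a median of -0.02 and a mean of 0.08, and that call was lost without Col-0×Per-1 replicate 2 (0.75) or Col-0 replicate 3 (0.334).

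**Figure D4:**
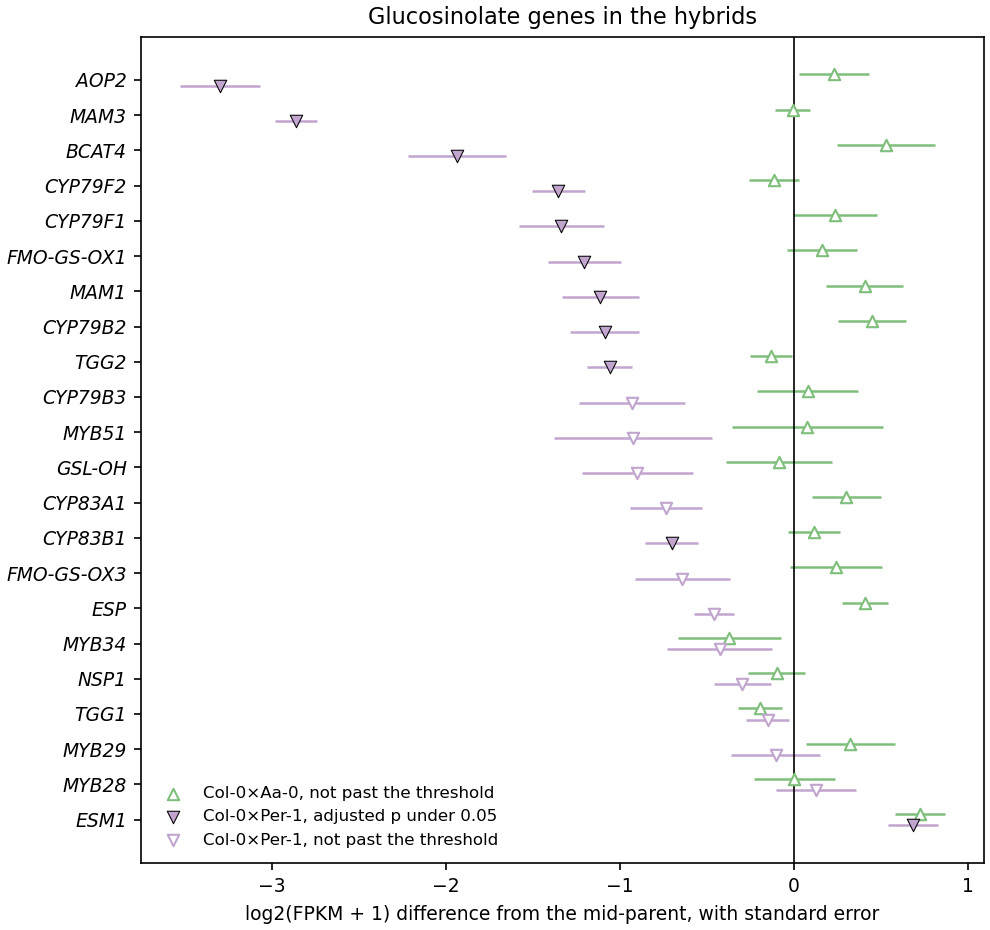
Deviation of 22 glucosinolate genes (y axis) from the mid-parent of each hybrid in log2(FPKM + 1) (x axis, with standard errors, n = 2 per hybrid). Filled marks passed an adjusted p of 0.05 by limma: 10 genes lie below and ESM1 above the mid-parent in Col-0×Per-1, and 0 passed in Col-0×Aa-0.

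By limma 442 genes deviated from the mid-parent in Col-0×Per-1, 63 above and 379 below, with a median of -0.14 over all tested genes. Median-ratio scaling gave 109 above and 157 below, and quantile normalization 110 and 145. With the replicate number as a block 274 genes deviated, against 233 in Col-0×Aa-0, and with Col-0 replicates 3 and 4 alone 2568. The hybrid differed from Col-0 in 3426 genes (458 higher, 2968 lower; 869 and 865 with median-ratio scaling) and from Per-1 in 817 (414 higher, 403 lower). Compared with Col-0, 15 of 21 ribosomal protein genes were lower (18 when adjusted over the list alone; adjusted p = 8.98e-05; adjusted p = 0.718 with an estimated correlation), and 13 of 24 cell cycle genes (15 when adjusted over the list alone; adjusted p = 0.00251; adjusted p = 0.622 with an estimated correlation). By cameraPR the cell cycle call against Col-0 ended with Col-0 replicates 1 and 2 alone (adjusted p = 0.102) or the replicate number as a block (0.0565). The ribosomal call ended with Col-0 replicates 3 and 4 alone (0.0733). The photosynthesis, plastid-encoded and mitochondrially encoded lists were also called against Col-0 (adjusted p = 0.347, 0.796 and 0.347 with an estimated correlation). Compared with Per-1, 5 of 21 salicylic acid genes were lower (PR1, GRX480, PR5, NUDT6 and EDS1; 9 when adjusted over the list alone; adjusted p = 0.00034; adjusted p = 0.608 with an estimated correlation) and 9 of 24 NLR genes higher (adjusted p = 2.84e-06; adjusted p = 0.608 with an estimated correlation).

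Of the 4426 genes separating Per-1 and Col-0, 1849 were at the lower parent's level in Col-0×Per-1, 476 at the higher parent's, 263 between, and 1804 were not resolved. The low-parent share was 79.5% (exact binomial 95% interval 77.8 to 81.2%, genes treated as independent, p = 4.71e-190) and differed from that of the other hybrid (Fisher's exact test, odds ratio 0.138, p = 4.63e-83, genes treated as independent). It was 89.4% where Col-0 was the higher parent (1617 genes against 192) but 45.0% where Col-0 was the lower (232 against 284, exact binomial p = 0.0247). In both cases more of these genes were classed at the Per-1 level than at the Col-0 level. Col-0 had more libraries than Per-1, so a gene midway is more easily classed at the Per-1 level. The binomial tests for both hybrids take no account of this imbalance. The counts of 232 against 284 therefore cannot show that the hybrid was nearer to Per-1. How much of either excess the imbalance gives was not tested, and no split by parent is given for scaled values. The pooled share turned to 43.0% with median-ratio scaling, 42.1% with quantile normalization and 45.0% for genes with a log2 difference of at least 1. Over all tested genes, 34 of these 4426 included, 31 were above and 73 below both parents, or 48 and 26 with median-ratio scaling and 50 and 21 with quantile normalization.

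These counts also depended on single libraries. Leaving out Col-0×Per-1 replicate 2 gave 40 deviations from the mid-parent, 358 differences from Col-0, 422 from Per-1, 13 genes outside both parents and a low-parent share of 46.9%. Leaving out its replicate 1 gave 72 deviations, 1483 and 535 differences and 49 genes outside both. Without Per-1 replicate 1 or 2 the deviations numbered 64 or 210, the differences from Per-1 344 or 492, and the genes outside both 30 or 58. Without Col-0 replicate 1 or 3 there were 266 or 223 deviations and 65 or 69 genes outside both, and without Col-0 replicate 3 there were 2281 differences from Col-0.

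Whether the hybrids deviated differently was tested directly. The deviation was larger (less negative) in Col-0×Aa-0 by 4.01 ± 0.15 for AT5G41660 (log2, standard error, adjusted p = 3.7e-06), 3.53 ± 0.30 for AOP2 (adjusted p = 0.0013) and 2.85 ± 0.16 for MAM3 (adjusted p = 3.6e-05). AT5G41660 was listed at 0 in Col-0, Aa-0 and Col-0×Aa-0, and MAM3 was below 1 FPKM in all of them, so for these genes the difference only repeats the deviation in Col-0×Per-1. HPL1 differed by 2.72 ± 0.31, although its parental levels differ between crosses and the call just failed without Per-1 replicate 2 (adjusted p = 0.0501) or Col-0×Per-1 replicate 2 (0.0506). The glucosinolate list differed (AOP2, MAM3, BCAT4 and CYP79F2 of 22 members; 12 when adjusted over the list alone; adjusted p = 1.88e-31; adjusted p = 0.214 with an estimated correlation). The BCAT4 call was lost when any library but Col-0×Per-1 replicate 2 was left out (adjusted p from 0.0515 to 0.169), and with median-ratio (0.0657) and quantile scaling (0.0761). In total 40 genes differed, 31 with the larger deviation in Col-0×Aa-0 and 9 in Col-0×Per-1, or 24 and 15 with quantile normalization. The count fell to 8 without Col-0×Aa-0 replicate 2, 15 without its replicate 1, 16 and 21 without Col-0×Per-1 replicates 2 and 1, 10 and 15 without Per-1 replicates 1 and 2, and 23 without Aa-0 replicate 1.

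Deviating genes overlapped between the hybrids. AT2G47115 was below the mid-parent in both (-1.59 and -1.92 on the log2 scale), and AT4G13615 above it in both (1.17 and 0.84). AT2G47115 was at 6.98 FPKM in Col-0, 34.3 in Aa-0, 41.2 in Per-1, and 6.245 and 5.605 in the hybrids. The ubiquitin gene UBQ6 (AT2G47110) went the opposite way, at 57.5, 0.11, 0.03, 49.2 and 44.4. Different assignment of reads would give this as well and was not tested for these 2 genes. The Col-0×Aa-0 call of AT4G13615 was lost without Col-0 replicate 2 or any single Aa-0, Per-1 or Col-0×Aa-0 library (adjusted p from 0.0531 to 0.477). In all 14 genes were above and 13 below in both (20 and 12 with median-ratio scaling), where independent lists would share 0.0806 and 0.419, and 100 simulations of unchanged hybrids with the same Col-0 libraries shared at most 0 and 1. In opposite directions there were 0 and 1, the latter being AT5G45472. Across genes, which are not independent replicates, the deviations correlated at r = 0.172 (covariance 0.0125) against a simulated mean of 0.106 and highest of 0.175 (covariance 0.00517 and 0.00921). So r lay within the simulated values, near the highest, and the covariance lay above all of them. The simulations drew each library independently and so lack the differences between pairs of Col-0 libraries. With split Col-0 controls r was -0.252 (replicates 1 and 2 for Col-0×Aa-0) or 0.254 (the reverse). Those fits shared 21 genes above and 49 below, or 12 and 18. With all Col-0 libraries, 22 of the 28 shared genes found in the reference overlap another gene. Without overlapping genes 3 were shared, and leaving out a hybrid library gave 3 or 4 (Col-0×Aa-0) and 8 or 9 (Col-0×Per-1). The number was also 13 without Aa-0 replicate 1 and 12 or 16 without Per-1 replicate 1 or 2.

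Genes near 0 in one parent (at most 0.1 FPKM in each library) and at 5 FPKM or more in every library of the other were compared with the hybrids. Values near 0 need not mean that a gene was silent: the ubiquitin gene UBQ6, at 0.03 ± 0.0424 FPKM in Per-1 and 57.5 ± 1.17 in Col-0, was among them. RPP2A and AT3G47250 met these bounds in both crosses, the latter at 83.6 ± 5.26 FPKM in Col-0, 39.8 ± 1.72 in Col-0×Aa-0 and 43.9 ± 6.33 in Col-0×Per-1. The 37 genes near 0 in Aa-0 had median ratios to Col-0 of 0.546 and 0.491 in the Col-0×Aa-0 libraries, and the 40 near 0 in Per-1 had 0.502 and 0.461 in the Col-0×Per-1 libraries. In the hybrid without that parent the ratios were 0.656 and 0.612 for the former and 0.647 and 0.558 for the latter. Most genes of either list were on both, so that hybrid too had a parent near 0 for them. Its ratios do not show the level with 2 active alleles. The 11 genes near 0 in Col-0 and high in Aa-0 stood at 0.437 and 0.479 of Aa-0 in Col-0×Aa-0 and at 0.285 and 0.234 in Col-0×Per-1. The 16 near 0 in Col-0 and high in Per-1, AT2G15555 among them (40.2 ± 2.25 FPKM in Per-1, 20.14 ± 0.608 in the hybrid), stood at 0.453 and 0.330 of Per-1 in Col-0×Per-1 and at 0.0556 and 0.0379 in Col-0×Aa-0. Of these 16, 5 were also among the genes high in Aa-0, and the other 11 stood at 0.225 and 0.212 in Col-0×Per-1.

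Of the genes chosen in advance for every comparison, FLC and PR1 are given above. CCA1, a core clock gene, was at 60 ± 59.3 FPKM in Col-0 (SD, n = 4), 24.1 ± 1.82 in Aa-0, 24.0 ± 3.16 in Per-1, 18.3 ± 1.39 in Col-0×Aa-0 and 41.9 ± 4 in Col-0×Per-1 (SD, n = 2 each). LHY was at 26.4 ± 28.5, 4.93 ± 0.764, 5.95 ± 0.148, 4.58 ± 0.170 and 9.45 ± 1.09 in the same order. Neither passed against Col-0 or a mid-parent (adjusted p from 0.609 to 1 by limma), and the direction followed the Col-0 libraries. Against replicates 1 and 2 alone both were lower in each accession (log2 difference of LHY -3.14 in Aa-0 and -2.91 in Per-1, of CCA1 -2.16 and -2.17), and against replicates 3 and 4 alone both were higher (LHY 1.13 and 1.36, CCA1 1.36 and 1.35). ARGOS, a promoter of organ growth, was at 1.93 ± 1.15 FPKM in Col-0, 1.535 ± 0.375 in Col-0×Aa-0 and 4.06 ± 0.792 in Col-0×Per-1, and did not pass in these comparisons. WUS, a gene of the shoot stem cell niche, was listed at 0 in every library and was not tested.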

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

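Every test of an explanation in this part was chosen only after the result it concerns had been seen.

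Within Col-0, the group with 4 libraries, single libraries lay far from the other 3 by Dixon's test, which picks out about 1 in 20 genes by chance. Of 126 genes examined 6 were found: WRKY70 at 86 FPKM in replicate 3 (26.5 to 31.3 in the others), RPL28A at 106 in replicate 1 (89.1 to 90.7), ATMG01080 at 3.37 in replicate 4 (4.25 to 4.34), FLC at 0.26 in replicate 1 (0 to 0.04), XCP1 at 13.2 in replicate 2 (12.4 in the others) and ATMG00830 at 0.76 in replicate 3 (up to 1.57). The share of plastid-encoded transcripts was 1.928% in replicate 3 and 3.094 to 3.273% in the others.

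Other results were picked out because the deviation from the mid-parent differed between the hybrids, which held for 40 genes. On the log2 scale the deviation of Col-0×Aa-0 minus that of Col-0×Per-1 was 4.01 for AT5G41660, 3.53 for AOP2, 2.85 for MAM3, 2.72 for HPL1, 2.69 for IGMT2, 2.47 for BCAT4, -1.89 for AT2G04170, -1.87 for AT4G37553 and -1.59 for AT5G45472. Several of these calls ended when 1 library was left out: IGMT2 for 9 of the 12 libraries (adjusted p from 0.0601 to 0.213; not Col-0 replicates 1 and 4 or Col-0×Aa-0 replicate 1), AT2G04170 for both Aa-0 and both Col-0×Per-1 libraries, Per-1 replicate 1 and Col-0×Aa-0 replicate 2 (0.0543 to 0.143), AT4G37553 for Aa-0 and Per-1 replicates 1 and all hybrid libraries (0.0541 to 0.0923), and AT5G45472 for Col-0×Aa-0 replicate 2 (0.0527). BCAT4 was lost for every library but Col-0×Per-1 replicate 2 (0.0515 to 0.169), and HPL1 for Per-1 replicate 2 (0.0501) and Col-0×Per-1 replicate 2 (0.0506). Lists with such a difference were salicylic acid and immune response (adjusted p = 0.011), jasmonate (0.000409), glucosinolate (1.88e-31), photosynthesis (0.0435), ribosomal proteins (1.9e-06), flowering time (0.0418), plastid-encoded (9.63e-08) and mitochondrially encoded genes (2.98e-08). With an estimated correlation none passed, the lowest adjusted p being 0.167. List calls also ended without single libraries. The immune, photosynthesis and flowering time calls ended without Col-0×Aa-0 replicate 2 or Col-0×Per-1 replicate 2, among others. The plastid-encoded call ended without Col-0×Per-1 replicate 2.

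The first pattern concerned 433 genes called in both accessions in the same direction with a log2 difference of at least 1. In 108 of them both hybrids stood less than 0.25 of the way from Col-0 to the accession on the log2(FPKM + 1) scale, in 99 within 0.25 on either side of Col-0 and in the others further beyond it (down to -0.699). Of the 108, 76.9% overlap another annotated gene, against 22.8% of the other 325. Where 1 gene of an overlapping pair had changed, its partner moved the opposite way in 64.4% of 118 pairs, as different assignment of reads in the accession libraries would give. In the hybrids the genes of these opposite pairs had a median position of 0.119 and an upper quartile of 0.286. For the 276 genes that overlap none the values were 0.454 and 0.642. Variants of the accessions against the reference stay open. On this log2 scale a hybrid with 1 active allele can lie well below the middle, also under 0.25, where the accession is lower. Regulators from Col-0 acting on both alleles stay open, since the ratio of the shares (3.38) only restates the pattern, and so does whether the accession libraries were made or processed differently.

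The second pattern was the larger number of deviations from the mid-parent in Col-0×Per-1 (442) than in Col-0×Aa-0 (41). Scaling did not account for the whole difference, since the ratio was still 6.05 with median-ratio scaling. The count itself depended on scaling, as 219 of the 442 calls in Col-0×Per-1 held with median-ratio scaling. For the excess below the mid-parent that scaling decides nothing, because it centres the libraries, and 59% of the calls (157 against 109) were still below. Much of the count needed both Col-0×Per-1 libraries: without replicate 2 it was 40 against 27 in Col-0×Aa-0 (ratio 1.48) and without replicate 1 72 against 27 (2.67). These fits leave 1 library against 2. In fits where each hybrid lost 1 of its own libraries, the lower count of Col-0×Per-1 was 8 times the higher count of Col-0×Aa-0. Either Col-0×Per-1 library alone thus gave more calls than either Col-0×Aa-0 library alone. These counts come from different fits with 1 library left in the hybrid. How much of the difference was due to a single library therefore stays open. The choice of Col-0 libraries stays open: the ratio was 1.58 with replicates 1 and 2 and 57.1 with replicates 3 and 4, against 10.8 with all. With the replicate number as a block it was 1.18 (274 against 233), a fit in which Col-0 replicates 3 and 4 have no partner in the other groups.

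The third pattern concerned genes called higher in Per-1 by a log2 difference of at least 2 that overlap no other gene. In Col-0×Per-1 27 of these 89 (30.3%) had an FPKM within 0.15 of the Col-0 to Per-1 distance from Col-0, 8 of them below Col-0, against 2 of 58 genes high in Aa-0 (3.45%) in Col-0×Aa-0 (Fisher's exact p = 3.13e-05, genes treated as independent). Among the 27 was AT2G47115, whose values mirrored those of UBQ6 although it is not annotated as overlapping another gene. Libraries from Col-0 alone or from a cross with Aa-0 are argued against by the 16 genes near 0 in Col-0 and high in Per-1, whose median ratio to Per-1 was at least 0.33 in each library, against at most 0.0556 in Col-0×Aa-0, and by FLC (36.8 FPKM, against 0.075 in Col-0 and 0.045 in Col-0×Aa-0). A cross with an accession other than the Per-1 measured stays open. Genes near 0 in Per-1 had an upper quartile of the ratio to Col-0 of at most 0.619, lower than 2 active alleles would give, but another accession may be near 0 in the same genes. Long missing chromosome segments in the Per-1 parent would place such genes side by side, but 0.943 of 10000 shuffles had as many neighbours. Neighbours were counted among the 89 genes alone, so the shuffles cannot decide about short segments. An immune or jasmonate state of the Per-1 seedlings may be involved for PR1, PR5 and JAZ10, and the test could not tell (Fisher's exact p = 0.362).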

How the results depend on the processing

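Of 146 called results for named genes 71 kept their direction and their side of the threshold under every alternative, and of 56 list calls 0 did. With an estimated correlation 0 lists were called, and with fry 34, of which 20 were among the 56. Where no cause is given below, the cause was not tested.

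A mean of at least 5 FPKM, which tests fewer genes, left 1436 genes between Aa-0 and Col-0, 2546 between Per-1 and Col-0, 814 between Aa-0 and Per-1, 132 and 188 between Col-0×Aa-0 and Col-0 or Aa-0, 2071 and 313 between Col-0×Per-1 and Col-0 or Per-1, and 111 between the hybrids. Deviations from the mid-parent were then 19 in Col-0×Aa-0 and 115 in Col-0×Per-1, with 9 different between hybrids, 1 and 40 outside both parents and 12 shared. Requiring a log2 difference of at least 1 gave, in the same order, 997, 1177, 818, 155, 303, 616, 480 and 198, then 24 and 124 deviations, 5 and 18 outside both parents and 9 shared. No filter gave 67 deviations in Col-0×Aa-0, 93 different between hybrids and 23 outside both parents in Col-0×Aa-0, and log2(FPKM + 0.1) gave 25, 16 and 4. The mean of log2 values as mid-parent gave 114 and 68, with 77 shared.

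With only the groups needed, which leaves fewer samples for the spread, the counts were 1578 between Aa-0 and Col-0, 199 and 254 between Col-0×Aa-0 and Col-0 or Aa-0, 2069 between Col-0×Per-1 and Col-0, 13 deviations in Col-0×Aa-0 and 8 shared. Without overlapping genes, an alternative added after the data were seen, they were 1912 between Aa-0 and Col-0, 252 between Col-0×Aa-0 and Aa-0, 479 between Col-0×Per-1 and Per-1, 5 and 237 deviations, 5 and 67 outside both parents and 3 shared. Col-0×Per-1 against Col-0 gave 1734 genes with median-ratio scaling and 1671 with quantile normalization, and its deviations 266 and 255.

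The Col-0 libraries chosen mattered. Replicates 1 and 2 alone gave 2598 genes between Aa-0 and Per-1, 2351 between Col-0×Aa-0 and Col-0, 1223 between the hybrids, 374 deviations in Col-0×Aa-0, 87 different between hybrids, 43 outside both parents in Col-0×Aa-0 and 134 shared. Replicates 3 and 4 alone gave 606 genes between Col-0×Aa-0 and its Col-0 parent, 5314 for Col-0×Per-1, 1236 between the hybrids, 2568 deviations in Col-0×Per-1, 155 different between hybrids and 233 outside both parents in Col-0×Per-1. The replicate number as a block gave 1888 and 2265 genes against Col-0, 795 between the hybrids, 233 and 274 deviations, 25 different between hybrids, 32 outside both parents in Col-0×Aa-0 and 68 shared. Residuals of equal replicate numbers correlated between -0.585 and 0.369 over 10 pairs of groups, 3 of them above 0.1, and the numbers were taken as shared only as numbers.

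The low-parent share turned in Col-0×Aa-0, to 58.21% with Col-0 replicates 1 and 2 and 57.13% with the block. In Col-0×Per-1 the share turned to 42.99% with median-ratio scaling, 42.11% with quantile normalization and 44.97% with a log2 difference of at least 1, and was 46.89% (exact binomial p = 0.158) without Col-0×Per-1 replicate 2. The ratio of genes high in Aa-0 and near 0 in Col-0 was 0.4089 with bounds of 0.5 and 10 FPKM, against 0.458.

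With Col-0 replicates 1 and 2 alone the clock list turned and passed against the mid-parent of Col-0×Aa-0 (adjusted p = 0.000146) and Col-0×Per-1 (0.0394), LNK2 was lower in Per-1 than in Col-0 (log2 difference -0.976), and LHY (-1.50) and CCA1 (-0.68) were below the mid-parent in Col-0×Per-1. The block gave 0.00221 and 0.0405 for the list, -0.976 for LNK2 and -1.50 for LHY. With replicates 3 and 4 alone LNK2 (1.13), P5CS1 (0.66), LHY (1.13) and CCA1 (1.36) were higher in Aa-0 than in Col-0, and LHY (1.36) and CCA1 (1.35) in Per-1. The clock list then passed against the mid-parent of Col-0×Aa-0 (0.0259), and the cold and drought list turned in Col-0×Aa-0 against Col-0 (0.00707) and against the mid-parents of Col-0×Aa-0 (0.00132) and Col-0×Per-1 (0.0299). Other lists that turned were NLR genes in Col-0×Aa-0 with the mean of log2 values as mid-parent (0.00492), ribosomal proteins in Col-0×Aa-0 against the mid-parent without its replicate 2 (0.00137, while without its replicate 1 the list passed at 3.57e-06 and over all omissions its adjusted p ran up to 0.787 without Aa-0 replicate 1), and with fry leaf growth (0.0106) and clock genes (0.0378) in Per-1 and leaf growth in Col-0×Per-1 against Col-0 (0.022).

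Leaving out 1 library, which leaves a group of 2 with 1 sample assumed to vary like the other groups, gave 1218 to 2759 genes between Aa-0 and Col-0, 1807 to 4681 between Per-1 and Col-0, 722 to 1717 between Aa-0 and Per-1 (1087 without Aa-0 replicate 2, 864 without Per-1 replicate 2), and 140 to 356 between the hybrids (183 without Col-0×Aa-0 replicate 1, 167 and 144 without Col-0×Per-1 replicates 1 and 2). Col-0×Aa-0 had 156 to 464 genes against Col-0, 291 to 464 against Aa-0 and 4 to 35 deviations (19 without Aa-0 replicate 1, 23 without either Per-1 library, 5 without its replicate 1, 27 without either Col-0×Per-1 library). Col-0×Per-1 had 358 to 3639 against Col-0 (2281 without Col-0 replicate 3, 1483 without its replicate 1), 344 to 784 against Per-1 (492 without Per-1 replicate 2, 535 and 422 without its own), and 40 to 457 deviations (266 and 223 without Col-0 replicates 1 and 3, 64 and 210 without Per-1 replicates 1 and 2, 72 without its replicate 1).

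The difference between hybrids ran from 8 to 30 genes (23 without Aa-0 replicate 1, 10 and 15 without Per-1 replicates, 15 without Col-0×Aa-0 replicate 1, 21 and 16 without Col-0×Per-1 replicates). Genes outside both parents ran from 1 to 10 in Col-0×Aa-0 (2 without its replicate 1) and from 13 to 95 in Col-0×Per-1 (65 and 69 without Col-0 replicates 1 and 3, 30 and 58 without Per-1 replicates, 49 without its replicate 1). Shared deviations ran from 3 to 23 (13 without Aa-0 replicate 1, 12 and 16 without Per-1 replicates, 4 without Col-0×Aa-0 replicate 1, 9 and 8 without Col-0×Per-1 replicates). The low-parent share ran from 22.38 to 42.18% in Col-0×Aa-0 and from 46.89 to 81.44% in Col-0×Per-1, list calls from 49 to 62, named calls from 101 to 134, and the Aa-0 ratio from 0.3891 (without Aa-0 replicate 2) to 0.4792 (without Col-0×Aa-0 replicate 1).

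Absolute depth is unknown, and Col-0×Per-1 replicate 2, without which its group had the fewest differences from Col-0 and from the mid-parent, had the lowest relative depth (0.66), so low values there are the least precise.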

Other observations

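The accessions Aa-0 and Per-1 were also compared with each other. PDF1.2 stood at 3.63 ± 0.255 FPKM in Aa-0 and 120 ± 10.6 in Per-1 (SD, n = 2 each; log2 difference -4.71 ± 0.81, adjusted p = 0.00482 by limma), and RPP2B at 0.22 ± 0.0283 against 28.7 ± 2.69. Of 21 salicylic acid and immune genes 9 were lower in Aa-0 (15 when adjusted over the list alone; list adjusted p = 3.34e-05; adjusted p = 0.68 with an estimated correlation), and of 18 jasmonate genes 7 (12 when adjusted over the list alone, with 1 higher; 0.0061; adjusted p = 0.68 with an estimated correlation), the jasmonate list being lost without Per-1 replicate 1 (0.146). In all 1713 genes differed, 910 higher and 803 lower in Aa-0, with 722 left without Per-1 replicate 1, 864 without its replicate 2 and 1087 without Aa-0 replicate 2.

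Between the hybrids, FLC was at 0.045 ± 0.0636 FPKM in Col-0×Aa-0 and 36.8 ± 3.10 in Col-0×Per-1 (SD, n = 2 each; log2 difference -5.18 ± 0.16, adjusted p = 9.7e-08 by limma), SOC1 at 38.2 ± 5.29 against 16.3 ± 0.785, and ESP (AT1G54040) at 513 ± 18.1 against 22.2 ± 0.665. Of 22 glucosinolate genes MAM1, TGG2, BCAT4 and ESP were higher in Col-0×Aa-0 and MAM3 lower (8 and 1 when adjusted over the list alone; list adjusted p = 3.75e-07; adjusted p = 0.736 with an estimated correlation). The plastid-encoded and mitochondrially encoded lists were also called between the hybrids (adjusted p = 0.811 and 0.736 with an estimated correlation). In all 351 genes differed, 213 higher and 138 lower in Col-0×Aa-0, or 169 and 197 with median-ratio scaling. The count was 183 or 140 without Col-0×Aa-0 replicate 1 or 2 and 167 or 144 without Col-0×Per-1 replicate 1 or 2.

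The Col-0 replicates 1 and 2 differed from 3 and 4, the pairs used as alternatives, in 2554 genes. Of 20 clock genes 9 were higher in replicates 1 and 2, with LHY by 4.26 and CCA1 by 3.52 on the log2 scale, and 9 lower, with ELF4 at -4.96 and TOC1 at -2.59. PRR7 (adjusted p = 0.0632) and ZTL (0.503) did not pass, and the clock list, with members going both ways, did not pass as a list (0.428). Lists that passed with the preset correlation were plastid-encoded genes (8 of 77 higher, adjusted p = 0.000136), flavonoids (4 of 7 higher, 0.000351), cold and drought (3 of 24 higher and 10 lower, 0.016), chlorophyll biosynthesis (6 of 18 higher and 2 lower, 0.0401) and photosynthesis, which passed downwards (0.016) although 6 of 34 members were higher and 1 lower. The lower member was RBCS1A (-14.3 on the log2 scale), and without it the list did not pass and pointed upwards (0.175). The share of plastid-encoded transcripts did not follow the pairs: it was 3.10% and 3.27% in replicates 1 and 2, 1.93% in replicate 3 and 3.09% in replicate 4. No result with an estimated correlation is given for these lists. No label gives a time of day or batch for these libraries.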
